A study of Homo sapiens with 4 samples.

How the data were processed

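MCF-7, an oestrogen receptor positive human breast cancer cell line, was treated for 48 h with CMCAAT, the conditioned medium of cancer-associated adipose tissue. Control cells received serum-free DMEM/F12 medium with 0.5% bovine serum albumin. Total RNA of each of 4 CMCAAT-treated cultures was hybridised on its own 2-colour whole-genome array against 1 pool of RNA from 3 control cultures. Per the labels, the treated RNA carried Cy3 in replicates 1 and 4 and Cy5 in replicates 2 and 3, and the control pool carried the other dye. The labels do not say whether the 4 conditioned media came from different tissue samples, so whether the spread between arrays covers variation between tissues is not known.

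The deposited scanner files gave the median spot intensity and the median local background intensity of each channel, per the file headers, with neither background correction nor normalisation. They also held a log10 ratio of red over green that the scanner software computed after background subtraction and dye normalisation, per the file headers. The deposited spot flags are other values, 0 or 1, that mark control spots, saturation, uneven spots and signal well above background, per the file headers. The headers name Feature Extraction 10.7.1.1 and array design 014850, whereas the submitters' processing notes name version 8.5.1.1 of the same software. Which of these made the files was not settled. The authors' value table held the log10 ratio of each array to within 0.005, with a median of 0 on each array, red over green and not turned for the swapped dyes. The comparison of each column with its array settled scale and direction. No file gave the mean spot signal, for which the fixed plan had asked, so the median spot signal was used. No sample column stayed unmapped (0).

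Intensities were read into limma 3.58.1 under R 4.3.3. Background was corrected by normexp with an offset of 50, which pulls the ratios of dim probes towards 0. Each array was normalised by loess with control spots at weight 0. Spots that the software called non-uniform were left out, 1, 31, 10 and 3 spots of replicates 1 to 4. No spot was saturated (0). Every ratio was turned to treated over control. Spots of 1 probe were averaged. A probe was kept where it was well above background on at least 3 of the 4 arrays in the treated or in the control channel, which left 27033 of 41000 probes. The probe with the highest mean signal stood for a gene with several probes. Of 4749 such genes, 89 (1.87%) had probes called in opposite directions.

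The files name probes by accession. A RefSeq gene table of assembly GRCh38.p14 named 26222 of the 41000 probes (64%), and the other 14778 kept their accession. The 20465 genes tested comprised 13114 named genes and 7351 unnamed transcripts. The headers give genome build hg19, which differs from that assembly, so no coordinates are printed. Probes of near-identical genes (the complement C4 genes, the SPANX family, HLA genes, metallothioneins, IFITM genes, AKR1C genes, S100A7 and its copy) can bind the transcripts of each other, and the symbol of such a gene is uncertain.

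The model held the treatment and a dye term for each gene. The treatment coefficient was tested against 0 with limma's moderated statistic and Benjamini-Hochberg adjustment, with 2 residual and 3.45 prior degrees of freedom. The dye term takes a bias that is equal in both orientations out of the spread, and the orientations are balanced, so it leaves the fold change as it is. The control pool is 1 RNA sample on all 4 arrays. The test therefore leaves out the spread between control cultures, and a deviation of the pool would enter each ratio alike. All 4 arrays lay on the same slide and were scanned together, so there was no slide or scan batch to test. Values are fitted log2 ratios with their moderated standard error (SE), which leaves out the gap between dye orientations that the dye term takes up. Its median over genes was 0.041, against 0.059 for the plain standard error of the 4 array values. Each orientation holds other cultures, so the smaller SE may leave out a difference between cultures as well, and with no dye term 9067 genes were called. The number of arrays limits the precision.

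A gene that was not well above background on all 4 arrays in 1 channel has only a bound, for the mean over arrays and not for each array. It sets the mean normalised log2 signal of the bright group against the mean, over arrays, of the dim signal or the lowest signal of probes well above background, whichever was higher. This held for 106 genes in the control channel and 273 in the treated channel. No list median changed when such members were set to their bound.

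In simulated ratios of these 20465 genes with 200 genes changed, the same model and test recovered 78% of changes of log2 0.5, 98% of changes of 1 and 100% of changes of 2 and 3. Of 193 calls, 5 (2.59%) were false. The shifted list was found (1) and no other list was called (0). The simulation began from finished ratios and drew noise for each gene on its own, at its spread around the fit. It held no correlation between genes, no deviation of a control pool and far fewer changed genes than the 11752 called in the data. Its rates of false calls of genes and lists need not hold for the data.

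Before the data were examined, 30 gene lists, the named genes and the alternatives were fixed. The named genes are the 12 largest rises and the 12 largest falls among called genes with a RefSeq symbol and the same sign on all 4 arrays, 25 genes chosen for the question, and the 4 members with the smallest p in each list (all of them in a list with fewer than 4). Symbols that begin with LOC were left out of the first part. Lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation, which rests on 2 residual degrees of freedom. Fry was run beside it. Fry does not compare a list with other genes.

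The alternatives were no background correction, an offset of 16, the scanner software's log ratio, the authors' value table, median centring, Aquantile or scale normalisation between arrays, no filter on dim probes or a stricter one, non-uniform spots kept, the mean of a gene's probes, each probe on its own, no dye term, an intensity trend with a robust prior, array weights, each dye orientation alone, each replicate left out, and a minimum change of 2-fold. A two-sided test against a change of 1.2-fold (limma treat) and a count over named genes were added after seeing the data.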

Results

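Transcripts of MCF-7 cells, a human breast cancer line that carries the oestrogen receptor, were compared after 48 h in CMCAAT, the conditioned medium of cancer-associated adipose tissue, and in serum-free control medium. The question was which genes of the cancer cells change when they meet the factors that adipose tissue next to a tumour releases. Oncostatin M, a cytokine of the IL-6 family that acts through JAK-STAT3, was among the factors of interest. The data comprised 4 arrays, each with the RNA of 1 treated culture against the same pool of 3 control cultures. Treated RNA was in Cy5 on 2 arrays and in Cy3 on 2 arrays. Probes well above background made up 63.66% to 66.82% of all probes in the treated channel and 65.1% to 68.3% in the control channel. The median background-subtracted signal was 116, 173, 189.5 and 116 for the treated RNA of replicates 1 to 4, and 202, 132.5, 136.5 and 206 for the control pool.

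The largest rises after CMCAAT were in TCN1, S100A8, S100A7, SUSD3, C4B and S100A9. The transcript of TCN1, a vitamin B12 carrier, was at least 31.9-fold higher on average over arrays. This is a bound, since its control signal was not well above background on any of the 4 arrays. Its fitted log2 ratio was 5.18 ± 0.18 (SE of the fit with the dye term, 4 arrays). The array values ran from 3.83 to 6.42 (plain SE 0.57), so single arrays lay below the bound. The SE after each ± is that of the fit, which leaves out the gap between dye orientations. S100A8 and S100A9, the subunits of calprotectin, rose by 4.95 ± 0.36 (30.9-fold) and 3.70 ± 0.16 on the log2 scale. S100A7, psoriasin, rose 28.8-fold (4.85 ± 0.32). SUSD3, a membrane protein with a sushi domain, rose 16.7-fold (4.06 ± 0.12). C4B, complement component 4, rose 13.8-fold (3.79 ± 0.12), although its probe may not separate it from its near-identical copy. SERPINA3, the acute phase protein antichymotrypsin, rose 9.78-fold (3.29 ± 0.13), and MUCL1, a small mucin of breast epithelium, rose 9.12-fold (3.19 ± 0.13). CP, ceruloplasmin, rose 8.77-fold (3.13 ± 0.22) and CFB, complement factor B, rose 6.50-fold (2.70 ± 0.15), with a control signal well above background on 2 of 4 arrays for each. RHOBTB3, an atypical Rho-family protein, rose 8.01-fold (3.00 ± 0.07), and NTN4, the laminin-related protein netrin 4, rose 7.64-fold (2.93 ± 0.06). NTN4 was at 3.48 and 3.25 on the arrays with treated RNA in Cy3 and at 2.40 and 2.61 on those with Cy5 (plain SE 0.26).

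The largest falls were in SPANX genes, CCN2, ACKR3 and ATF3. SPANXA1 and SPANXD, cancer-testis antigens with near-identical copies that the probes may not separate, had log2 ratios of -5.13 ± 0.23 and -4.66 ± 0.17. CCN2, connective tissue growth factor, fell by 4.73 ± 0.36 on the log2 scale. ACKR3, an atypical receptor for the chemokine CXCL12, fell by 4.27 ± 0.23, and the stress-responsive transcription factor ATF3 fell by 3.73 ± 0.40. ANXA1 and ANXA3, annexins that bind membranes with calcium, had log2 ratios of -3.27 ± 0.09 and -3.15 ± 0.06. IGFBP5, a binding protein of insulin-like growth factors, fell by 3.23 ± 0.15. ID1, an inhibitor of basic helix-loop-helix factors, fell by 3.15 ± 0.07, and TNFRSF11B, the decoy receptor osteoprotegerin, fell by 3.14 ± 0.05. SCUBE2, a secreted protein, fell by 3.09 ± 0.09, and CAV1, the coat protein of caveolae, fell by 3.02 ± 0.17. These 24 genes were chosen among called genes with the same sign on all 4 arrays, so the choice fixed their calls and signs. Their limma adjusted p lay between 1.65e-05 (TNFRSF11B) and 0.000982 (ATF3).

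**Figure D1:**
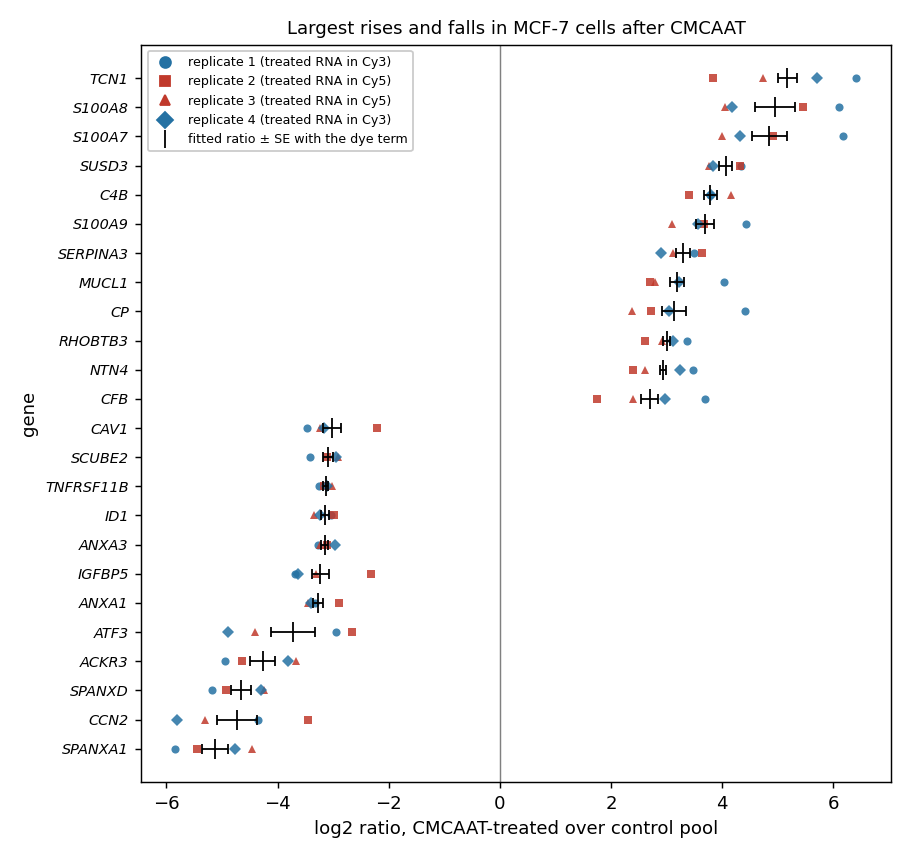
Log2 ratio of treated cells over the control pool (x axis) for the 12 largest rises and 12 largest falls among named genes (y axis). Coloured points are the 4 arrays, marked by replicate and by the dye of the treated RNA. Black bars are the fitted ratio ± its SE with the dye term. The points of each gene lie on 1 side of 0, as the choice of these genes required. The TCN1 value rests on a control signal not well above background.

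Of 20465 genes tested, 11752 (57.4%) differed from the control pool at limma adjusted p below 0.05, 5551 higher and 6201 lower. Most of these changes were small: the median absolute log2 ratio of the called genes was 0.29. A change of at least 2-fold was reached by 629 of them, 244 higher and 385 lower. At least 4-fold changes numbered 38 higher and 55 lower. Of the called genes, 10604 (90.2%) had the same sign on all 4 arrays. At an unadjusted p below 0.05 the count was 12868. The share of lower calls was 52.8%. With median centring in place of loess it was 74.7%, with 1786 higher and 5260 lower, and with the scanner software's log ratio 47.1%, with 6724 higher and 5987 lower. Over genes, the ratios correlated at 0.93 (replicates 1 and 4) and 0.90 (replicates 2 and 3) between arrays of the same dye orientation, and at 0.81 to 0.84 between arrays of opposite orientation. Genes are not independent replicates.

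**Figure D2:**
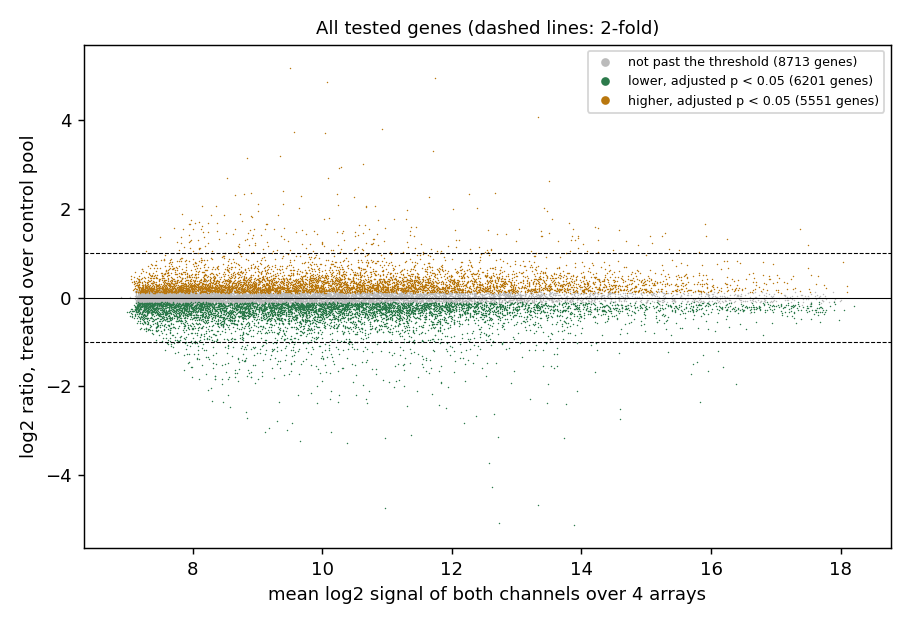
Mean log2 signal of both channels over 4 arrays (x axis) against the log2 ratio of treated cells over the control pool (y axis), 1 point per tested gene, coloured by direction among calls at adjusted p below 0.05. Dashed lines mark 2-fold changes, beyond which lie 629 of the 11752 called genes.

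Among the 30 gene lists, 13 shifted up and 6 shifted down against all other genes at camera adjusted p below 0.05. None (0) of the 19 calls held with an estimated correlation (adjusted p = 0.314 to 0.525 with an estimated correlation). That setting also ended the call of the cell cycle list, whose estimate (-0.006) was below the preset. The end of a call there does not by itself show that correlation between genes undid it. Counts of members that rose or fell are at adjusted p below 0.05 over all genes tested. The counts adjusted over the list alone were the same unless both are given. Medians, means and the sizes of rises and falls are on the log2 scale, each gene with the SE of its fit.

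The lists of acute phase genes and of complement and coagulation genes shifted up. Of 11 measured acute phase genes, 8 rose and 1 fell, with a median log2 ratio of 1.55 and adjusted p = 0.00138 (adjusted p = 0.495 with an estimated correlation). SERPINA1, the protease inhibitor antitrypsin, rose by 2.69 ± 0.09 beside SERPINA3, CFB and CP. LCN2, the iron-siderophore binder lipocalin 2, rose by 1.55 ± 0.30, from a control signal well above background on 2 of 4 arrays. The list's median was 2.92 on replicate 1 and 0.95 to 1.21 on the other arrays. The median was 0.09 with no filter on dim probes, 0.69 with the stricter filter and 3.34 with the scanner software's log ratio, and the call held in each. Of 19 complement and coagulation genes, 12 rose and 5 fell (median 0.45, adjusted p = 0.0161; adjusted p = 0.449 with an estimated correlation). Here F12, coagulation factor XII, rose by 0.99 ± 0.03 and CD59, which blocks the membrane attack complex, by 1.19 ± 0.05, while CFD, the adipokine complement factor D, fell by 0.81 ± 0.06. The median was 0.13 with no filter on dim probes, where the call held. The scanner software's log ratio ended this call, and adjusted p ran from 4.86e-07 to 0.449 over the alternatives. Both lists hold C3 and CFB.

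The list of S100 and epidermal differentiation proteins split. Of 23 measured genes, 10 rose and 7 fell, or 10 and 11 adjusted over the list alone. The list was not called (adjusted p = 0.858), and its median of -0.05 differed in sign from its mean of 0.62 and from the direction of the test, which was up. With median centring it was called up (adjusted p = 0.00438), at a median of -0.06. SERPINB1, an inhibitor of neutrophil proteases, rose by 0.66 ± 0.04, and S100A10, the annexin A2 partner, fell by 1.21 ± 0.06.

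Genes of antigen presentation rose together. All 27 measured members of the list were higher, on a median log2 ratio of 0.84 (0.67 to 0.86 over the 4 arrays) and adjusted p = 3.29e-12 (adjusted p = 0.449 with an estimated correlation). For 3 of the 27, 1 channel was not well above background on any array, so they passed the filter through the other channel alone. With the stricter filter the median was 0.90, and the call held. PSMB9, a subunit of the immunoproteasome, rose by 1.96 ± 0.04 and B2M, the light chain of MHC class I, by 1.21 ± 0.04. TAP1, which carries peptides into the endoplasmic reticulum, rose by 1.07 ± 0.03, and HLA-C by 1.05 ± 0.03, with the caution that HLA probes can bind related HLA transcripts. Interferon-stimulated genes rose as a list, with 21 of 36 higher and 5 lower (median 0.32, adjusted p = 2.91e-05; adjusted p = 0.449 with an estimated correlation). IFITM1, IFITM2 and IFITM3, membrane proteins that restrict virus entry, rose by 1.95 ± 0.04, 1.38 ± 0.04 and 1.39 ± 0.04. IFITM1 was at 1.70 and 1.63 on the arrays with treated RNA in Cy3 and at 2.195 and 2.27 on those with Cy5 (plain SE 0.17). UBE2L6, the conjugating enzyme of ISG15, rose by 0.98 ± 0.04. The median of the interferon list was 0.18 with no filter on dim probes and 0.19 with median centring, and the call held in both.

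The list of JAK-STAT3 and IL-6 family response genes moved both ways and was not called (12 of 33 higher, 13 lower, adjusted p = 0.917). Fry gave adjusted p = 0.876 for a shift in 1 direction and 0.000987 for change in either direction, the latter at or below 0.0217 in all 30 lists. Among receptors and signal transducers, OSMR, the oncostatin M receptor subunit, rose by 1.24 ± 0.07, IL6ST, the shared subunit gp130, by 0.46 ± 0.05 and STAT3 by 0.67 ± 0.06, while LIFR, the LIF receptor subunit, fell by 1.00 ± 0.05. The transcription factor CEBPD rose by 1.68 ± 0.04 and the NF-kB cofactor BCL3 by 0.92 ± 0.07. SOCS1, a feedback inhibitor of JAK kinases, fell by 1.58 ± 0.09. JUNB, a subunit of AP-1, and TIMP1, an inhibitor of metalloproteinases, had ratios of -1.0 ± 0.05 and -0.78 ± 0.04. SOCS3, the feedback inhibitor induced by STAT3, had a log2 ratio of 0.03 ± 0.05 (adjusted p = 0.629), with values of -0.10, 0.00, 0.10 and 0.12 on replicates 1 to 4. With the mean of all probes of a gene, the ratio of SOCS1 was -0.99 and that of LIFR -0.63. IL6ST was at 0.29 on the Cy5 arrays alone and at 0.69 with the scanner software's log ratio, and its call held in both. The NF-kB list was not called either (6 of 18 higher and 8 lower, or 7 and 8 adjusted over the list alone; adjusted p = 0.917). Its median was 0.00 and its mean -0.06, with the test down. In it, SOD2, mitochondrial superoxide dismutase, rose by 0.91 ± 0.08 and the chemokine CXCL12 by 0.63 ± 0.05, while the cytokine IL11 fell by 1.51 ± 0.10 and NFKBIA, the NF-kB inhibitor, fell by 0.45 ± 0.04.

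Immediate early genes and the feedback regulators of MAPK fell. Of 27 measured genes, 24 fell and 2 rose (median -0.83, adjusted p = 5.13e-06; adjusted p = 0.525 with an estimated correlation), and the median was below 0 on 4 of 4 arrays. EGR1, a zinc-finger transcription factor, the ERK phosphatase DUSP6 and the transcription factor MYC had ratios of -1.64 ± 0.12, -1.49 ± 0.09 and -0.82 ± 0.06. Of 20 TGF-beta and SMAD targets, 16 fell and 3 rose (median -0.87, adjusted p = 2.66e-05; adjusted p = 0.47 with an estimated correlation). ID3 and ID2, relatives of ID1, had ratios of -2.01 ± 0.04 and -1.17 ± 0.04, and PMEPA1, a TGF-beta feedback inhibitor, of -1.55 ± 0.05. JUNB stands in this list, the immediate early list and the JAK-STAT3 list.

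Mesenchymal genes of the epithelial-mesenchymal transition fell, with 15 of 23 lower and 2 higher, or 16 and 2 adjusted over the list alone (median -0.36, adjusted p = 0.00103; adjusted p = 0.495 with an estimated correlation). The actin-binding CALD1 fell by 1.27 ± 0.05, thrombospondin THBS1 fell by 1.24 ± 0.05, and vimentin, VIM, fell by 0.50 ± 0.09. The matricellular protein CCN1 fell by 2.73 ± 0.13. The median of this list was -0.085 with no filter on dim probes, where the call held. Genes of epithelial junctions and luminal keratins fell as well, with 16 of 27 lower and 3 higher, or 17 and 3 adjusted over the list alone (median -0.20, adjusted p = 0.00324; adjusted p = 0.449 with an estimated correlation). In that list TJP1, a tight junction scaffold, fell by 0.69 ± 0.04 and the claudin CLDN4 fell by 0.66 ± 0.04, whereas the mucin MUC1 rose by 2.35 ± 0.03 and the epithelial transcription factor ELF3 by 1.51 ± 0.05. CDH1, E-cadherin, had a log2 ratio of -0.20 ± 0.04 (plain SE 0.18; adjusted p = 0.00716), but it was -0.50 on the 2 arrays with treated RNA in Cy5 and 0.11 on the 2 with Cy3. It was at -0.33 with median centring and at -0.34 with scale normalisation. Its call ended on the Cy3 arrays alone, with no dye term and with scale normalisation (adjusted p 0.00188 to 0.253 over the alternatives). The list of matrix remodelling and adhesion genes was not called (8 of 32 higher and 13 lower, or 8 and 14 adjusted over the list alone; adjusted p = 0.336). CTSD, the lysosomal protease cathepsin D, rose by 2.00 ± 0.12, while TIMP2 fell by 0.75 ± 0.03 and integrin ITGB4 fell by 0.60 ± 0.04.

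Genes of the cell cycle rose by moderate amounts. Of 49 measured genes, 45 rose and none fell (0), with a median log2 ratio of 0.44 (0.35 to 0.58 over the 4 arrays) and adjusted p = 4.78e-14 (adjusted p = 0.314 with an estimated correlation). The mitotic kinases PBK and PLK1 rose by 0.80 ± 0.03 and 0.67 ± 0.04, and survivin, BIRC5, by 0.78 ± 0.04. The proliferation marker MKI67 rose by 0.32 ± 0.04; median centring (0.19) ended that call (adjusted p 0.000922 to 0.19 over the alternatives). CCND1, cyclin D1, was at 0.01 ± 0.05 (adjusted p = 0.900). Ribosome biogenesis and MYC target genes rose, with 23 of 30 higher and 4 lower, or 24 and 4 adjusted over the list alone (median 0.34, adjusted p = 1.24e-05; adjusted p = 0.525 with an estimated correlation). BOP1, WDR12 and LYAR, factors of ribosome assembly, rose by 0.72 ± 0.04, 0.52 ± 0.04 and 0.57 ± 0.04, while ODC1, the polyamine enzyme, fell by 0.61 ± 0.04. MYC itself stands in this list and fell by 0.82 ± 0.06.

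Ribosomal protein transcripts differed by dye orientation. Over all 4 arrays 26 of 40 were lower and 1 higher (median -0.18, adjusted p = 8.79e-05; adjusted p = 0.449 with an estimated correlation). The list's median was -0.42 and -0.45 on the 2 arrays with treated RNA in Cy3 and 0.09 and 0.14 on the 2 with treated RNA in Cy5. RPL28, a protein of the large subunit, had ratios of -0.85 and -0.85 on the former arrays and 0.09 and 0.17 on the latter. On the Cy5 arrays alone the list was called up (adjusted p = 0.0101) and on the Cy3 arrays alone down. Its median was -0.075 with scale normalisation and -0.068 with the scanner software's log ratio, which ended the call, and adjusted p ran from 2.01e-09 to 0.449 over the alternatives.

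Oestrogen-responsive genes rose more often than they fell, with 20 of 38 higher and 10 lower (median 0.32, adjusted p = 0.0125; adjusted p = 0.525 with an estimated correlation). The transcript of the receptor itself, ESR1, had a log2 ratio of -0.36 ± 0.10 (adjusted p = 0.0250). GREB1, a receptor cofactor, rose by 1.47 ± 0.07, the receptor kinase RET by 2.25 ± 0.10, the transcription factor XBP1 by 1.18 ± 0.05, PKIB, an inhibitor of protein kinase A, by 1.47 ± 0.06 and PGR, the progesterone receptor, by 0.39 ± 0.04. TFF1, trefoil factor 1, averaged 0.80 ± 0.04, but was at 0.14 and 0.22 on the arrays with treated RNA in Cy3 and at 1.48 and 1.37 on those with Cy5 (plain SE 0.36); its call ended on the Cy3 arrays alone and with scale normalisation (adjusted p 1.08e-05 to 0.0772 over the alternatives). IGFBP5 fell in this list. The median of the list was 0.19 on the Cy3 arrays alone, where the call held. The call ended with scale normalisation between arrays and with the scanner software's log ratio (adjusted p 0.000164 to 0.525 over the alternatives). That of ESR1 ended without replicate 1 (adjusted p = 0.0957) or replicate 2 (0.0829) and with the scanner software's log ratio (0.071), and adjusted p ran from 0.000664 to 0.145 over the alternatives.

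Genes of fatty acid and triglyceride synthesis rose more often than they fell. Of 19 fatty acid and triglyceride synthesis genes, 14 rose and 2 fell (median 0.35, adjusted p = 0.000181; adjusted p = 0.449 with an estimated correlation). The elongase ELOVL5 rose 3.03-fold (SE 0.05 on the log2 scale), DGAT2, which makes triglycerides, rose by 1.65 ± 0.08 and FASN, fatty acid synthase, by 0.50 ± 0.04, while the acyl-CoA synthetase ACSL3 fell by 0.49 ± 0.03. Of 28 genes of fatty acid handling and PPAR targets, 16 rose and 6 fell (median 0.20, adjusted p = 0.0163; adjusted p = 0.449 with an estimated correlation). The fatty acid carrier FABP5 rose by 1.53 ± 0.05, the fatty acid receptor CD36 by 1.48 ± 0.10 and the lipid droplet protein PLIN5 by 0.74 ± 0.05, whereas ACAA2, a thiolase of fatty acid oxidation, fell by 0.75 ± 0.04 and PLIN2, another lipid droplet protein, fell by 0.40 ± 0.08. CPT1A, which admits fatty acids to mitochondria, was at 0.08 ± 0.04 (adjusted p = 0.154), but was called up on the Cy5 arrays alone (0.25, adjusted p = 0.0392), with the scanner software's log ratio (0.14, 0.028) and with the mean of all probes (0.11, 0.0357). The median of this list was 0.07 with median centring and 0.11 with no filter on dim probes, where the call held, and the scanner software's log ratio ended the call (adjusted p 0.00219 to 0.449 over the alternatives). The cholesterol list was not called (13 of 27 higher, 6 lower, adjusted p = 0.170), but was called up with each probe on its own (adjusted p = 0.0233) and on the Cy3 arrays alone (0.0413). In it, the isomerase IDI1 fell by 0.49 ± 0.05 and the reductase DHCR7 rose by 0.47 ± 0.06; on the Cy3 arrays alone they were at -0.26 and 0.30, and the calls held. HMGCS1, the synthase at the start of the pathway, was at -0.01 ± 0.05 (adjusted p = 0.866). LDLR, the LDL receptor, had a log2 ratio of -0.19 ± 0.05 (adjusted p = 0.0224), a call that ended without replicate 3 (adjusted p = 0.0945) or replicate 4 (0.101), with adjusted p from 0.0104 to 0.213 over the alternatives. It was at -0.31 with median centring and, no longer called, at -0.12 on the Cy3 arrays alone and at -0.16 with the mean of all probes.

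The lists of hypoxia and glycolysis, of NRF2 and oxidative stress, of metallothioneins and of endoplasmic reticulum stress shifted up. Of 34 hypoxia and glycolysis genes, 20 rose and 7 fell (median 0.31, adjusted p = 0.00173; adjusted p = 0.47 with an estimated correlation). The glycolytic enzymes LDHA, HK2 and ALDOC rose by 1.07 ± 0.04, 0.85 ± 0.05 and 0.57 ± 0.03, while ADM, adrenomedullin, which hypoxia induces, fell by 1.42 ± 0.09. LDHA was at 0.83 and 0.70 on the arrays with treated RNA in Cy3 and at 1.41 and 1.33 on those with Cy5 (plain SE 0.18). Of 25 NRF2 and oxidative stress genes, 19 rose and none fell (0; median 0.50, adjusted p = 6.82e-06; adjusted p = 0.449 with an estimated correlation). The aldo-keto reductases AKR1C3 and AKR1C1 rose by 2.34 ± 0.08 and 1.76 ± 0.12, ferritin heavy chain FTH1 by 0.76 ± 0.04 and malic enzyme ME1 by 0.80 ± 0.05. Of 14 metallothionein and zinc transport genes, 9 rose and 2 fell (median 0.60, adjusted p = 0.00324; adjusted p = 0.449 with an estimated correlation). MT2A and MT1X rose by 0.84 ± 0.04 and 0.80 ± 0.03, and metallothionein probes can bind the transcripts of one another. Of 30 genes of endoplasmic reticulum stress and ATF4 targets, 16 rose and 4 fell (median 0.15, adjusted p = 0.00385; adjusted p = 0.449 with an estimated correlation). SDF2L1, a chaperone partner, rose by 0.55 ± 0.04 and asparagine synthetase ASNS by 0.41 ± 0.03. ATF3 stands in this list as well and fell by 3.73 ± 0.40. It was the 1 member called lower at 2-fold or more, against 2 called higher. The median of this list was 0.02 with median centring and 0.26 on the Cy3 arrays alone, and the call held in both.

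The remaining response lists were not called. Of 23 p53 targets, 8 rose and 8 fell, or 9 and 8 adjusted over the list alone (adjusted p = 0.847; median 0.07, mean -0.07, test up). BTG2, an antiproliferative factor, rose by 1.31 ± 0.05 and the kinase PLK2 fell by 1.59 ± 0.07. Of 16 glucocorticoid response genes, 7 rose and 7 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.997). ERRFI1, a feedback inhibitor of the EGF receptor, fell by 2.18 ± 0.06 and GADD45B, a stress sensor, fell by 1.68 ± 0.04. Of 19 heat shock genes, 7 rose and 6 fell (adjusted p = 0.917; median -0.04, mean -0.02, test up). The mitochondrial chaperone HSPE1 rose by 0.67 ± 0.05 and the cochaperone BAG3 fell by 0.59 ± 0.05.

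Markers of other cell types of adipose tissue did not rise as lists. Of 10 measured adipocyte markers, 4 rose and 2 fell (adjusted p = 0.493); CD36 was among the former, and CFD and PPARG, the adipogenic nuclear receptor, which fell by 0.70 ± 0.09, among the latter. PLIN1, a lipid droplet protein of adipocytes, was at least 1.47-fold higher on average over arrays, with a control signal not well above background on any array. Its log2 ratio was 0.14 on replicate 2 and 0.65 to 0.81 on the others. On the Cy5 arrays alone it was 0.40, no longer called (limma adjusted p = 0.0784). Of 9 fibroblast and stromal markers, 4 fell and none rose (0; median -0.16, adjusted p = 0.041; adjusted p = 0.47 with an estimated correlation). The collagen genes COL5A1 and COL6A1 had ratios of -1.70 ± 0.05 and -1.34 ± 0.04. The call of the fibroblast list ended without replicate 4 (adjusted p = 0.0557), and its median was -0.09 without replicate 3, -0.03 with no filter on dim probes, -0.06 with the stricter filter and -0.71 with the scanner software's log ratio. It also ended with no filter on dim probes, with the stricter filter, with scale normalisation, with the scanner software's log ratio and on the Cy5 arrays alone (adjusted p 0.0125 to 0.47 over the alternatives). Of 7 leukocyte markers, 2 rose and 1 fell (adjusted p = 0.917; median 0.00, mean -0.03, test up), and CSF1R, a macrophage growth factor receptor, fell by 0.52 ± 0.10. Of 5 endothelial markers, 3 fell and none rose (0; adjusted p = 0.313), with VWF, von Willebrand factor, at -0.50 ± 0.07.

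**Figure D3:**
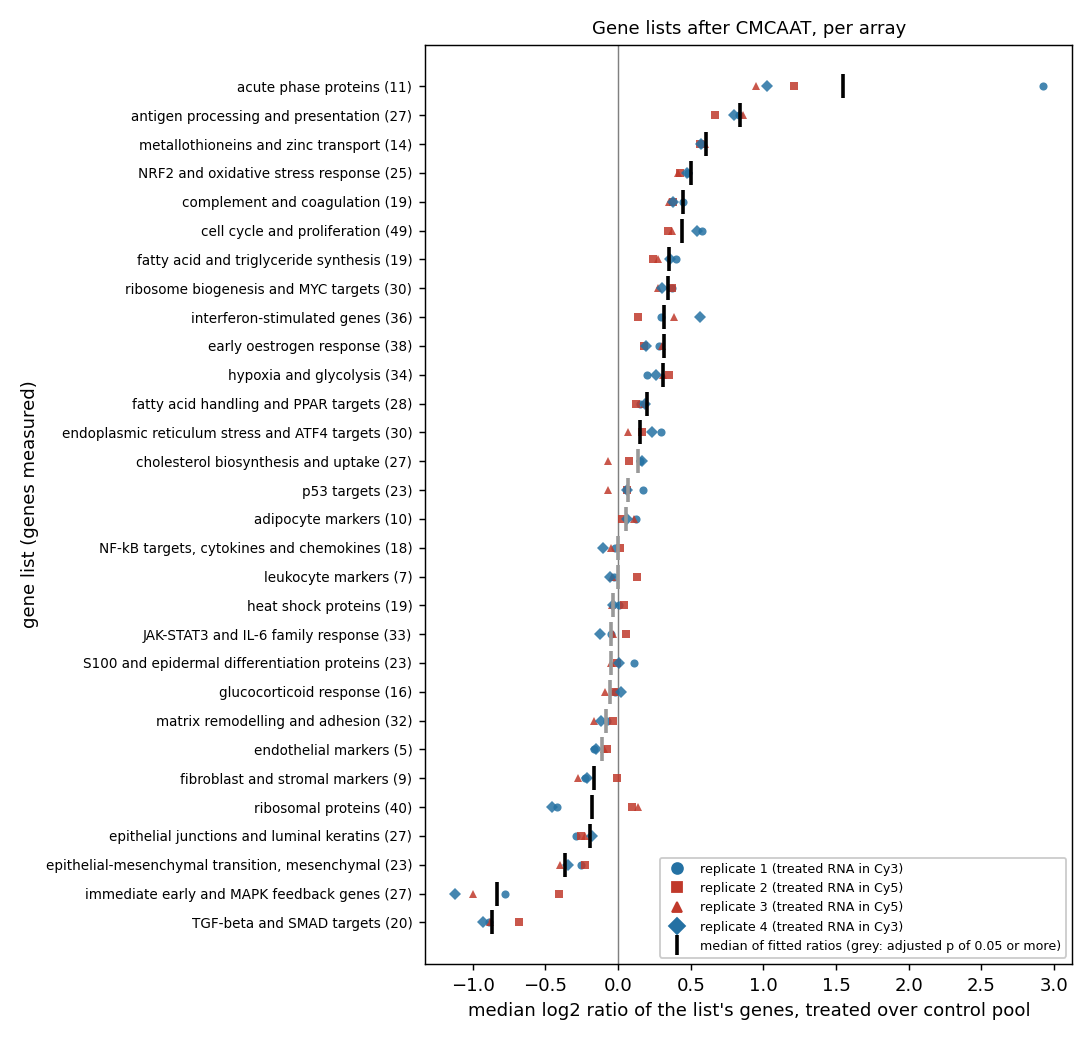
Median log2 ratio of treated cells over the control pool (x axis) in 30 gene lists (y axis, with the number of measured genes). Coloured points are the medians on the 4 arrays, marked by replicate and by the dye of the treated RNA, and vertical bars are the medians of the fitted ratios, black where camera adjusted p was below 0.05 at the preset correlation; the ribosomal protein points lie on both sides of 0 by dye.

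Scale normalisation between arrays ended the call of 36 of the 148 named genes, among them S100A7, S100A8, SUSD3, SERPINA3, LCN2, SPANXA1, SPANXD, ACKR3, CEBPD, BCL3, XBP1 and ESR1, at adjusted p from 0.0501 to 0.145 and with no change of sign; the Cy5 arrays alone ended those of 15, among them PGR, PLIN2, PLIN1, CSF1R, ESR1 and, with a change of sign, RPL28 and RPL6, at adjusted p from 0.0502 to 0.668. Ratios from the scanner software were 1.41 times as large over all genes by the slope, and the log2 values that moved by over 1.5 times were, among others, 8.41 for TCN1, 5.29 for CP, 4.77 for CFB, 3.46 for LCN2, 2.75 for PLIN1, 2.64 for CD36, 1.18 for PLIN5, 0.87 for PGR, -0.60 for PLIN2, -0.98 for VWF, -1.37 for PPARG, -1.51 for CSF1R and -4.65 for CAV1. With an offset of 16, PLIN1 was at 0.86. On the Cy5 arrays alone, CD36 was at 0.95. With the mean of all probes, ESR1 was at -0.23 and PLIN5 at 0.47. Median centring moved the medians of further called lists without ending the call: 0.20 for early oestrogen response and for hypoxia and glycolysis, 0.21 for ribosome biogenesis, 0.23 for fatty acid synthesis, -0.29 for epithelial junctions and -0.34 for ribosomal proteins.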

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

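The tests of the mean of the array medians and of probe pairs for the ribosomal protein list were chosen after the result was seen. Of 178 sets of 4 array values (named genes and list medians), 6 (3.4%) had 1 array far from the other 3. Independent values from 1 normal distribution would give about 5%. The arrays pair by dye orientation and the sets share genes, so that rate need not hold here. SERPINB1 was at 0.73 on replicate 4 and at 0.63 on each of the other arrays. IL11 was at -1.0 on replicate 2 and between -1.75 and -1.63 on the others. COL3A1 was at -0.04 on replicate 2 and between -0.27 and -0.24 on the others; its treated signal was well above background on 1 of 4 arrays, and its call ended without replicate 1 (adjusted p = 0.0611), 3 (0.0567) or 4 (0.0663), with adjusted p from 0.00142 to 0.224 over the alternatives. COL3A1 was at -0.88 with the scanner software's log ratio and at -0.34 with no background correction. VWF was at -0.20 on replicate 2 and between -0.61 and -0.57 on the others. The acute phase median was 2.92 on replicate 1 and between 0.95 and 1.21 on the others. The leukocyte marker median was 0.13 on replicate 2 and between -0.05 and -0.03 on the others. Replicate 2 was the far array in 4 of the 6.

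Of the tested genes, 57.4% differed from the control pool. Dye bias would turn the sign with the dye, but 97.65% of the 2000 genes with the smallest p on the Cy5 arrays kept their sign on the Cy3 arrays. That argues against dye bias for these genes. The weaker calls were not tested in this way. A deviation of the single control pool would enter all 4 arrays alike. There was 1 control RNA sample, so such a deviation and an effect of CMCAAT cannot be told apart for any gene, and the small changes are the most open to it.

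Ribosomal protein transcripts were lower on average but not on each array: the list's median was -0.43 with treated RNA in Cy3 and 0.12 with treated RNA in Cy5, and each pair of arrays alone gave a call in its own direction (adjusted p = 2.01e-09 and 0.0101). A dye bias equal in both orientations adds to the gap between these medians but cancels in their mean. The opposite signs (the test planned for it) therefore do not bear on the lower mean. Nor can the value of the mean test such a bias, which could not have moved it. With the dye term the 4 array medians averaged -0.16 (95% interval -0.22 to -0.10, 2 residual degrees of freedom). That interval takes the whole gap between the orientations as dye bias. If the gap is a difference between the cultures, the interval is too narrow and a lower mean is not shown. The interval ran from -0.11 to -0.01 with the scanner software's log ratio, but from -0.18 to 0.03 with scale normalisation and from -0.97 to 0.30 with median centring. A trend with signal strength was left undecided for the mean: the list's median lay at percentile 2.37 of 10000 random lists matched on mean signal, whose central 95% ran from -0.18 to 0.02. For the gap, dye bias of single probes and a difference between the cultures on the 2 pairs of arrays cannot be told apart. The dye coefficients of 2 probes of a gene correlated at 0.61 over 23 genes of the list (95% interval 0.26 to 0.82). The former explanation needs under 0.2 and the latter above 0.5, and the interval is not above 0.5 as a whole. Each culture was hybridised in 1 orientation alone. A dye bias shared by the probes of a gene would also make them correlate, and it was not tested.

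Arrays of the same dye orientation resembled each other more than arrays of opposite orientation. Dye bias of single probes goes with the probe's sequence and would leave the dye coefficients of different probes of a gene nearly unrelated, whereas a difference between the cultures on the 2 pairs of arrays would give them a high correlation. The correlation was 0.31 (95% interval 0.28 to 0.33, across 4749 genes, which are not independent replicates). That lies between the values the explanations predict, and they cannot be told apart, since each culture was hybridised in 1 orientation alone. A dye bias shared by the probes of a gene was not tested here either. For comparison, the treatment coefficient gave 0.86, and the difference between 2 arrays of the same orientation gave 0.56 and 0.44.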

How the results depend on the processing

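The test against 1.2-fold and the count over named genes (8142) were chosen after seeing the data. The count of 11752 changed genes (5551 higher, 6201 lower) fell to 7046 with median centring in place of loess (1786 higher), to 6088 with scale normalisation between arrays (2649 higher, 3439 lower) and to 6391 on the arrays with treated RNA in Cy5 alone (2916 higher, 3475 lower). The Cy3 arrays alone, with as many residual degrees of freedom, gave 10583. Stricter criteria gave 629 genes at 2-fold or more (244 higher, 385 lower) and 3127 beyond 1.2-fold (1419 higher, 1708 lower). The cause of the lower counts with median centring, with scale normalisation and on the Cy5 arrays was not tested. With each replicate left out in turn the count was 8989 to 10452. With no dye term it was 9067. The estimated correlation between genes left 0 of the 13 lists that shifted up and 0 of the 6 that shifted down, at adjusted p = 0.314 to 0.525 with an estimated correlation. It was estimated from 2 residual degrees of freedom. The estimate was below the preset 0.01 for the lists of cell cycle (-0.006), fatty acid handling (-0.003), metallothioneins (-0.023) and ribosomal proteins (-0.021). The calls of these lists ended as well, so a correlation above the preset is not what ended them. For the other lists, why the calls ended was not tested. The end of a call with this setting does not by itself show that correlation between genes undid it.

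Over 22 alternatives, the named genes and lists with a call at the main setting changed sign only between dye orientations. Other genes changed sign elsewhere too. Of calls shared with the main setting, 11357 of 11369 kept their sign with the mean of all probes and 14672 of 14770 with each probe on its own. The numbers were 6039 of 6053 on the Cy5 arrays alone and 9541 of 9549 on the Cy3 arrays alone. On the Cy5 arrays alone the ribosomal protein list was at 0.12 and was called up (adjusted p = 0.0101), against down at the main setting. RPL28 was at 0.13 and RPL6 at 0.035 there, and on the Cy3 arrays alone CDH1 was at 0.11, each no longer called (adjusted p = 0.166, 0.668 and 0.182).

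Among the named genes and the lists, the other changes of direction were in those without a call, whose values at the main setting lay near 0. For lists the direction is that of camera, so a median can keep its sign. The heat shock list was at -0.0023 with the scanner software's log ratio and the value table, -0.14 with median centring, -0.025 with scale normalisation, -0.046 with each probe on its own, -0.017 on Cy3 arrays and -0.069 to 0.0022 without 1 replicate. The S100 list was at -0.072 with no background correction, -0.031 with the scanner software's log ratio (-0.031 in the value table), -0.036 with scale normalisation and -0.071 to -0.026 without 1 replicate. The glucocorticoid list was at -0.062 with an offset of 16, -0.059 with the mean of all probes, 0.18 with each probe on its own, -0.0049 on Cy3 arrays and -0.076 to -0.025 without 1 replicate. The NF-kB list was at -0.082 with median centring, 0.023 with the stricter filter, 0.021 with each probe on its own, -0.0057 on Cy5 arrays and -0.023 to 0.028 without 1 replicate. The JAK-STAT3 list was at -0.0028 with the mean of all probes, 0.0019 on Cy5 arrays and -0.084 to -0.0073 without 1 replicate. The p53 list was at -0.030 with median centring and 0.011 on Cy5 arrays, and the leukocyte list at -0.090 on Cy3 arrays. HMGCS1 was at 0.0078 with the scanner software's log ratio and the value table, 0.029 with the mean of all probes, 0.12 on Cy3 arrays and -0.059 to 0.039 without 1 replicate. SOCS3 was at -0.10 with median centring and -0.023 to 0.083 without 1 replicate. CCND1 was at -0.11 with median centring, -0.15 on Cy3 arrays and -0.043 to 0.060 without 1 replicate. CPT1A was at -0.048 with median centring and -0.099 on Cy3 arrays, but was called up on Cy5 arrays (0.25), with the scanner software's log ratio and the value table (0.14) and with the mean of all probes (0.11). The cause was not tested for any of these.

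Of the other values over the alternatives, 3061 of named genes and 589 of lists kept their direction and their side of the threshold, 163 and 35 lost the call, and 6 and 3 gained it. The lists that gained it were the S100 list with median centring and the cholesterol list with each probe on its own and on Cy3 arrays. The minimum change of 2-fold made up 73 of the 163 losses of named genes. The estimated correlation made up 19 of the 35 losses of lists. Signal over background limits the dim genes: 106 tested genes have only a bound in the control channel and 273 in the treated channel. No paired analysis was possible because all 4 treated cultures were set against the same control pool.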

Other observations

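The gene lists in this part were chosen after seeing the data, and the test of the signature below was written before its result was seen. Genes of oxidative phosphorylation rose by small amounts: 43 of 53 measured subunit genes were higher and none lower (0), or 45 and 1 adjusted over the list alone, with a median log2 ratio of 0.21 and camera adjusted p = 3.34e-10 (adjusted p = 0.104 with an estimated correlation). COX6C, a subunit of cytochrome c oxidase, rose by 1.55 ± 0.04, NDUFS6 of complex I by 0.48 ± 0.04 and CYC1, cytochrome c1, by 0.44 ± 0.03. Proteasome subunits rose too, 28 of 31 higher and none lower (0; median 0.21, adjusted p = 5.19e-08; adjusted p = 0.219 with an estimated correlation), with PSMB6 at 0.49 ± 0.04 and PSMB3 at 0.52 ± 0.05. Both medians kept their sign in each dye orientation and under each scaling, at 0.09 (oxidative phosphorylation) and 0.10 (proteasome) with median centring.

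Of 19 amino acid activating tRNA synthetases, 15 rose and none fell (0; median 0.31, adjusted p = 1.52e-05; adjusted p = 0.219 with an estimated correlation), with FARSB at 0.50 ± 0.04 and YARS1 at 0.44 ± 0.05; the median was 0.20 with median centring. WARS1, GARS1 and AARS1 stand also in the list of endoplasmic reticulum stress and ATF4 targets. Lysosomal genes were not called as a list (15 of 35 higher, 8 lower, adjusted p = 0.140), although GLA, a lysosomal galactosidase, rose by 1.43 ± 0.11 beside CTSD. Androgen response genes were not called either (9 of 23 higher and 6 lower, or 9 and 7 adjusted over the list alone; adjusted p = 0.431).

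A candidate explanation for the falls of CCN1, CCN2 and TGFB2 is lower expression of the targets of YAP and TAZ, coactivators restrained by the Hippo pathway. Without these 3 genes, 13 of 17 measured members of a YAP and TAZ signature were lower and 1 higher, with a median log2 ratio of -0.93 and camera p = 4.32e-06 (p = 0.146 with an estimated correlation), as the hypothesis predicts. AMOTL2, DLC1, AJUBA and LATS2 had ratios of -1.92 ± 0.04, -1.93 ± 0.05, -1.89 ± 0.05 and -1.17 ± 0.05, whereas AXL was at -0.05 ± 0.08 and MYOF rose by 0.39 ± 0.03. The median of this reduced signature was -0.79 on the Cy5 arrays, -0.83 on the Cy3 arrays and -0.54 with no filter on dim probes. The reduced signature still held GADD45B, whose fall is given above with the glucocorticoid list. Lower MAPK or SMAD activity was not set against this hypothesis, and a deviation of the control pool stays open here too.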
